A study of Mus musculus with 4 samples.

How the data were processed

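Total RNA had been extracted with Trizol from 4 mouse liver tumor samples and amplified and biotin-labelled by in vitro transcription, per the labels' protocols, and each sample was hybridized to 1 Affymetrix mouse array. Groups and replicate numbers were taken from the sample labels: 2 samples of p53 off (0 days of doxycycline) and 2 of p53 on (8 days). The deposited table holds log2 values, 1 per probe set and array, that the authors made with RMA, a method of background correction, quantile normalization and summarisation, per the submitters' processing notes, which also name limma 3.14.4. The build and annotation used by the authors are not given in the sources used here. RMA gives no detection call, so dim probe sets carry values near background (lowest value 4.66, highest 14.9), and changes of dim genes can be compressed.

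The table held 45101 probe sets, of which 64 were control probe sets. A platform annotation table paired 34945 probe sets with exactly 1 gene symbol, 932 with several and 9160 with none; the last kind are unnamed here, not without a gene. Gene IDs of 34741 probe sets matched a RefSeq gene table (GRCm38.p6), which was used for names only, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean over the 4 arrays among probe sets of exactly 1 gene. This gave 18193 genes, with no filter on dim genes. Genes without such a probe set, among them the gene targeted by the hairpin and the driver oncogene, were not analysed here, and the change planned for the targeted gene has no value for that reason.

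Each gene was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3, statmod 1.5.0) as p53 on minus p53 off, without a block, with 2 residual and 5.47 moderated degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes, and adjusted p under 0.05 was called. The design cannot give a permutation test across 2 against 2 arrays a p under 0.05, so none was used for single genes. The 27 gene lists named 499 genes, of which 452 were measured. They covered p53 targets, the cell cycle, senescence, secreted factors, immune and stromal cell types, hepatocyte and progenitor genes, interferon and antigen presentation, RAS output, and metabolism. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

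The grouping, the fit, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named Cdkn1a, Mdm2, Ccl2 and Icam1, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap (leaving out predicted genes, clones and immunoglobulin or T cell receptor segments), and up to 4 called members of each list with the largest change, or the member with the smallest p where none was called. It named 111 genes, 54 of them with more than 1 probe set, and 1 of these (Bcl2l11) had a probe set past the threshold in the other direction. Another 30 genes were named after their values were seen. Also chosen after seeing the data were 3 gene lists (epithelial genes, mast cell genes and cholesterol synthesis genes), the scaling to spike-in controls, the crossed block and the permutation test between host cell types, which was run over 5 choices of types and genes.

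The alternatives were a block for the replicate number, quantile normalization, centring each array on its median, leaving out genes in the lowest 40% of mean values, the mean of all probe sets of a gene, the brightest probe set without a mark of likely cross-hybridization, trend and robust eBayes, array weights, a size threshold of 1 on the log2 scale, testing all probe sets, and leaving out each array in turn. In the last case the lone array of a group was assumed to vary like the other group. The fit was tested on simulated values for the 18193 genes of the comparison of p53 on with p53 off, with 50 genes changed at each size. It recovered 16% of genes changed by 0.5 on the log2 scale, 66% of those changed by 1, 80% of those changed by 2 and 100% of those changed by 4. Of 133 genes called there, 2 (1.5%) had not been changed. Only 200 genes were changed in the simulation, whereas 28.7% of genes were called in the data. The adjustment is therefore stricter in the simulation, and its rates do not carry over to the data.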

Results

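Gene expression was measured in 4 mouse liver tumor samples on Affymetrix mouse whole-genome arrays, 1 sample per array. The tumors grew from liver progenitor cells (LPCs, immature cells that can form hepatocytes and bile duct cells) placed into the livers of recipient mice. They were driven by oncogenic RAS and carried a tet-off hairpin against p53, a short hairpin RNA that is made until doxycycline is given. In 2 samples doxycycline had been given for 0 days, so the hairpin was on and p53 was suppressed (p53 off). In the other 2 it had been given for 8 days, so the hairpin was off and p53 was restored (p53 on). The median log2 value per array was 7.34 and 7.29 in p53 off and 7.39 and 7.39 in p53 on. The values of the p53 off arrays correlated across genes, 1 probe set each, with r = 0.9969 and those of the p53 on arrays with r = 0.9931. Pairs of arrays from different groups had r between 0.9652 and 0.9716; genes are not independent replicates. The first principal component held 85.9% of the variance. The difference between the 3' and 5' control probe sets, a sign of RNA quality, was taken for beta-actin and Gapdh. For beta-actin it was 0.395 and 0.262 in p53 off and 0.478 and 0.492 in p53 on. For Gapdh it was smaller in size, at -0.108 and -0.143 in p53 off and -0.0556 and -0.0208 in p53 on. Both moved with the groups, as did every gene list called here. The number of arrays limits the precision of every value. The p-values measure only the spread between these samples, which may be technical, because the labels do not say that replicates are separate animals or tumors. The targeted gene itself was not analysed here, so the state of p53 rests on the labels.

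The comparison of p53 on with p53 off asks what differs in established RAS-driven liver tumors after 8 days of doxycycline, which switches p53 back on. No sample had doxycycline without the hairpin. Effects of restored p53, of doxycycline itself and of 8 days of time therefore cannot be told apart. Genes of the cell cycle, ribosome production, and glycolysis were lower in p53 on, and p53 target genes, antigen presentation genes, and markers of macrophages, dendritic cells, blood vessels and fibroblasts were higher. These calls come from the list test camera with its preset correlation. With an estimated correlation all of them are lost (adjusted p from 0.509 to 0.648). That version has 2 residual degrees of freedom and could hardly call any list here, so its losses decide little. The rise of largest size among the named genes was that of Itga8, an integrin subunit, at 4.64 ± 0.22 on the log2 scale (SE, n = 2 against 2; 24.9-fold; limma adjusted p = 0.00043). Next came Agtr1a, an angiotensin II receptor, at 3.83 ± 0.18, and Meox2, a homeobox transcription factor, at 3.63 ± 0.20. They were followed by Steap4, a metalloreductase, at 3.60 ± 0.11 and Agtr2, the other angiotensin II receptor type, at 3.44 ± 0.22. Clec4a3, a C-type lectin receptor, rose by 3.37 ± 0.11 and the microfibril gene Fbn2 by 3.17 ± 0.086. Agmo, which cleaves ether lipids, rose by 3.15 ± 0.077, the matrix proteoglycan gene Lum by 3.01 ± 0.15 and Kctd12b by 2.91 ± 0.075. Synpr, which encodes a synaptic vesicle protein, fell by 3.69 ± 0.15 (12.9-fold; limma adjusted p = 0.00035). The changes of Klhl1 and Thsd7a were -3.64 ± 0.13 and -3.62 ± 0.091. The natriuretic peptide clearance receptor gene Npr3 changed by -3.54 ± 0.20 and Ankrd1, a nuclear ankyrin repeat protein gene, by -3.38 ± 0.19. Apob, the main protein of lipoproteins made by the liver, fell by 3.27 ± 0.21. The cadherin gene Cdh6 (-3.21 ± 0.071), Car8 (-3.13 ± 0.13), Glod5 (-3.08 ± 0.31) and Pcolce2 (8.00-fold lower) followed. Some sizes depended on the probe sets used: with the mean of all probe sets of a gene the change was 1.96 for Steap4, -1.82 for Npr3, -1.54 for Apob and -1.09 for Car8, and that of Meox2 was 2.16 in its probe set without likely cross-hybridization.

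Of 18193 genes tested with limma, 5223 (28.7%) passed an adjusted p of 0.05, 2550 of them higher and 2673 lower in p53 on. A change of at least 2-fold was found for 496 of the higher and 464 of the lower genes. Fewer genes were called without either p53 off array than without either p53 on array. Without a p53 off array the spread comes from the p53 on pair alone. That pair differed more (SD of the log2 difference 0.231, against 0.16 for p53 off). Lost calls can reflect that spread, as for Csf3r, at 0.37 and 0.39 without p53 off replicates 1 and 2, against 0.38. They can also reflect a changed size, as for Ccl2, at 1.28 and 0.79, against 1.03. Of the called genes 48.8% were higher, against 37.9% with each array centred on its median and 70% with arrays scaled to the hybridization spike-in controls.

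Of the 27 gene lists, camera with its preset correlation called 9 higher and 4 lower in p53 on. With an estimated correlation it called 0 of 27, with 1 list at an unadjusted p under 0.05. None of the calls given here therefore holds in that test, which has 2 residual degrees of freedom and could hardly call any list. For p53 target genes the estimate was -0.0181, below the preset 0.01, yet the unadjusted camera p went from 6.52e-10 to 0.0189. The losses are therefore weak evidence against a list. For the MHC class I pathway the estimate was 0.782, so p-values at the preset correlation may be too small. Fry, whose p tests whether the genes of a list move on balance 1 way without comparing them with other genes, called 10. Members of a list that are named because few changed, and not by the rule fixed in advance, were chosen after their values were seen; these are Epha2, Cdkn2b, Bhlhe40, Cdkn2a, Lmnb1, Icam2, Txk, Ccl6, Cxcl14, Serpina1c, Cyp2f2, Ahsg, Epcam, Sox9, Lyve1, H2-Eb1, Neu1, Pfkp and Adm.

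**Figure D1:**
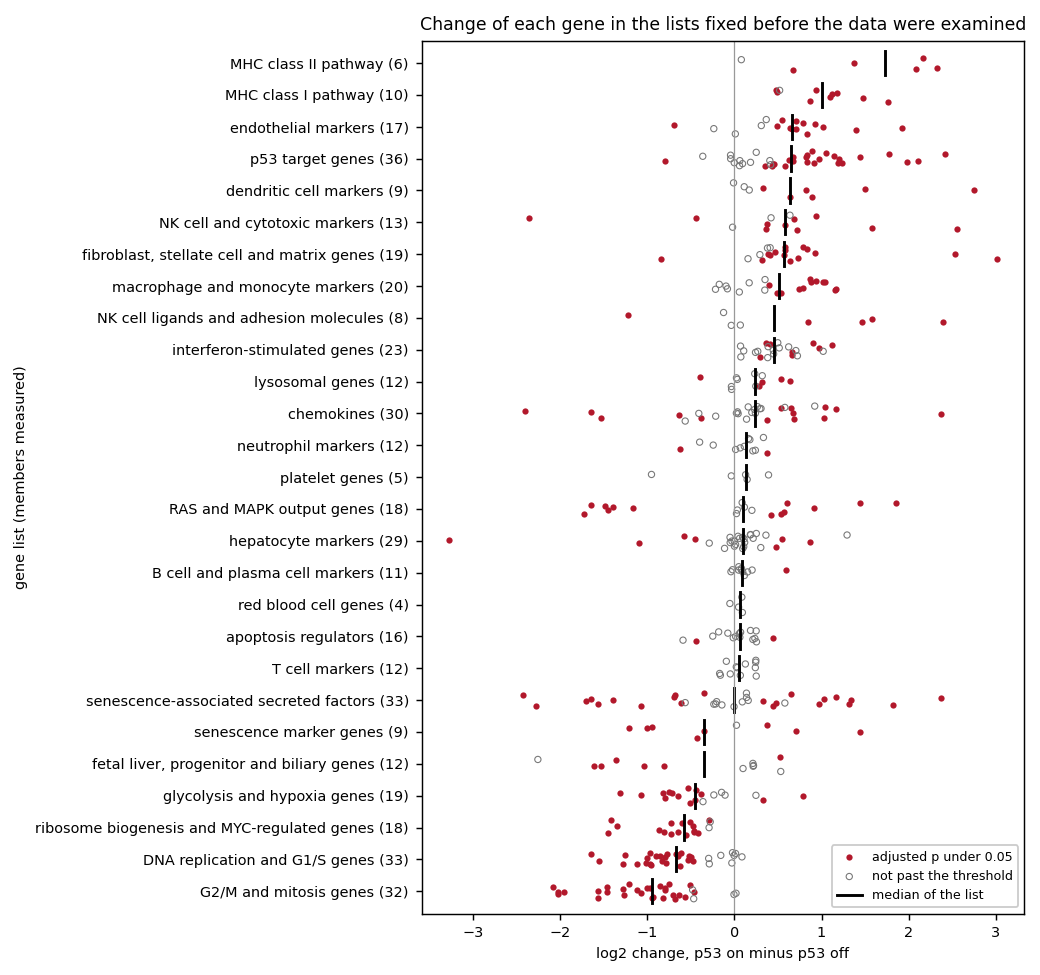
Log2 change from p53 off to p53 on of every measured gene in each of the 27 gene lists, 1 point per gene, with filled red points for genes past an adjusted p of 0.05, open points for the others and a black bar at the list's median. The medians run from -0.94 for G2/M and mitosis genes to 1.73 for the MHC class II pathway.

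Genes that p53 is known to activate were higher in p53 on. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 11.57 ± 0.16 to 13.00 ± 0.013 (mean log2 value ± SD, n = 2 each), a change of 1.44 ± 0.099 (SE; 2.71-fold; limma adjusted p = 0.00083). Mdm2, which encodes the ubiquitin ligase that degrades p53, rose by 0.83 ± 0.079 (1.78-fold). The largest changes in the list were those of Psrc1 at 2.42 ± 0.089, the death receptor family gene Eda2r at 2.11 ± 0.12, Trp53inp1 at 1.98 ± 0.11 and Dcxr, a xylulose reductase gene, at 1.77 ± 0.12; with the mean of all probe sets Psrc1 was at 1.05 and Trp53inp1 at 1.28. Of 36 measured p53 target genes 24 rose and 1, Epha2, fell (-0.80 ± 0.10); adjusted over the list alone, 26 rose and 2 fell. The list's median was 0.645 and its camera adjusted p was 5.87e-09, against an adjusted p = 0.509 with an estimated correlation and a fry adjusted p of 0.00553.

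Cell cycle genes were lower in p53 on. Among G2/M and mitosis genes, Ect2 changed by -2.08 ± 0.10, the ubiquitin-conjugating enzyme gene Ube2c by -2.03 ± 0.13 (4.07-fold lower), the cytokinesis scaffold gene Anln by -2.02 ± 0.11 and the kinesin gene Kif23 by -1.95 ± 0.18 (-1.01 with the mean of all probe sets). In this list 28 of 32 measured genes fell and 30 fell adjusted over the list alone. The median was -0.942 and the camera adjusted p was 6.72e-14, against an adjusted p = 0.611 with an estimated correlation and 0.0378 by fry. Of 33 DNA replication and G1/S genes 25 fell, and 27 adjusted over the list alone. The median was -0.669 and the camera adjusted p was 1.37e-10, against an adjusted p = 0.611 with an estimated correlation and 0.039 by fry. The genes that fell included Rrm2, a ribonucleotide reductase subunit gene, at -1.65 ± 0.15, the E2F repressor gene E2f8 at -1.55 ± 0.12 (-0.91 with the mean of all probe sets), the thymidine kinase gene Tk1 at -1.28 ± 0.19 and the cyclin gene Ccne2 at -1.25 ± 0.082. In the same samples the keratin genes Krt8 and Krt18 changed by -1.36 ± 0.10 and -1.61 ± 0.10. Of 30 epithelial genes, listed after the data were seen, 13 fell and 2 rose (median -0.13). The medians of macrophage, endothelial and fibroblast markers were 0.515, 0.659 and 0.57.

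Ribosome biogenesis and MYC-regulated genes were lower as well. The snoRNP genes Nop56 and Nop58 changed by -1.45 ± 0.096 and -1.41 ± 0.10, the nucleolar gene Nolc1 by -1.35 ± 0.11 and the ribosome assembly gene Wdr12 by -0.86 ± 0.15 (-0.48 with the mean of all probe sets). Of 18 measured genes 16 fell, and 17 adjusted over the list alone. The median was -0.58 and the camera adjusted p was 6.97e-09, against an adjusted p = 0.611 with an estimated correlation and 0.0378 by fry. Glycolysis and hypoxia genes were mostly lower: Pdk1, a kinase that inhibits pyruvate dehydrogenase, changed by -1.32 ± 0.13 (-0.55 with the mean of all probe sets), the angiogenic factor gene Vegfa by -1.07 ± 0.17, and the glycolytic enzyme genes Pgam1 and Pkm by -0.82 ± 0.099 and -0.80 ± 0.077. In this list 12 of 19 fell and 2 rose, Pfkp (0.33 ± 0.087) and Adm (0.79 ± 0.18), with the same counts adjusted over the list alone. The median was -0.45 and the camera adjusted p was 5.44e-05, against an adjusted p = 0.636 with an estimated correlation and 0.0378 by fry. As beside the cell cycle genes, Krt8 and Krt18 changed by -1.36 and -1.61 in these samples, while 13 of 30 epithelial genes fell and 2 rose (median -0.13). Macrophage, endothelial and fibroblast markers had medians of 0.515, 0.659 and 0.57. The limma calls were lost without p53 off replicate 2 for Wdr12 (adjusted p = 0.0679), Vegfa (0.0568), Pfkp (0.182) and Adm (0.139). They were also lost without p53 off replicate 1 for Wdr12 (0.0546), Pfkp (0.144) and Adm (0.063), and for Pfkp without p53 on replicate 2 (0.108) and with each array centred on its median (0.0796). Over all alternatives the adjusted p ran from 0.000913 to 0.0679 for Wdr12, from 0.00109 to 0.0568 for Vegfa, from 0.0153 to 0.197 for Pfkp, the highest with the mean of all probe sets of a gene (change 0.17), and from 0.00223 to 0.139 for Adm.

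RAS and MAPK output genes moved in both directions. Spry1, a feedback inhibitor of RAS signalling, rose by 1.85 ± 0.081, while Ier3 changed by -1.72 ± 0.087, the chromatin protein gene Hmga2 by -1.64 ± 0.075 and Myc by -1.48 ± 0.082. Of 18 measured genes 7 rose and 6 fell, with the same counts adjusted over the list alone. The median was 0.102 (0.186 without p53 off replicate 2, 0.214 with the mean of all probe sets, 0.178 with quantile normalization, 0.0277 with each array centred on its median and 0.233 with spike-in scaling) and the mean -0.114, and camera named the direction up (adjusted p = 0.79) and fry down (adjusted p = 0.396).

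Senescence marker genes also moved both ways. Besides Cdkn1a, the cell cycle inhibitor gene Cdkn2b rose by 0.71 ± 0.072 and Bhlhe40, a transcription factor gene, by 0.38 ± 0.083. The decoy receptor genes Tnfrsf23 and Tnfrsf22 changed by -1.20 ± 0.082 and -0.95 ± 0.095, the chromatin protein gene Hmgb2 by -1.01 ± 0.14 (-0.58 with the mean of all probe sets), Cdkn2a, which encodes p16 and p19ARF, by -0.43 ± 0.074 and the nuclear lamina gene Lmnb1 by -0.35 ± 0.077. Of 9 measured genes 3 rose and 5 fell, also adjusted over the list alone. The median was -0.347 (-0.216 with spike-in scaling) and the camera adjusted p was 0.355. The list was fixed without the direction that each gene takes in senescence. Its median, its counts and its camera p therefore do not test for senescence. Without p53 off replicate 2 the limma calls were lost for Bhlhe40 (adjusted p = 0.122), Cdkn2a (0.086) and Lmnb1 (0.156), each also without p53 off replicate 1 (0.11, 0.0521 and 0.0831), and without a p53 on array for Bhlhe40 (replicate 2, 0.0615) and Lmnb1 (replicate 1, 0.068). Their adjusted p ran from 0.00946 to 0.122, from 0.00518 to 0.086 and from 0.00987 to 0.156 over the alternatives, and Lmnb1 also lost its call with quantile normalization (0.0602) and with spike-in scaling (0.103; change -0.22), and was at -0.63 with the mean of all probe sets.

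Factors secreted by senescent cells split evenly, with 11 of 33 measured genes higher and 11 lower, over all genes and adjusted over the list alone. The chemokine gene Ccl8 rose by 2.37 ± 0.19 (5.17-fold) and the cytokine gene Il18 by 1.82 ± 0.10, whereas the cytokine gene Il6 changed by -2.43 ± 0.27 (5.39-fold lower) and Igfbp5, which encodes a binding protein of insulin-like growth factors, by -2.28 ± 0.25. The list's median was -0.0038 and its camera adjusted p 0.609, and the median was 0.127 with arrays scaled to the spike-in controls, -0.0785 with each array centred on its median, 0.0911 with dim genes left out, 0.0834 and 0.0188 without p53 off replicates 1 and 2, and -0.1 without p53 on replicate 2. The fall of Igfbp5 rests on 1 of its 2 probe sets: the mean of both was at -1.11, and the other changed by 0.065 (adjusted p = 0.566; range over the alternatives 0.000131 to 0.566).

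Of 30 chemokine genes 9 rose and 5 fell, and 12 rose and 6 fell adjusted over the list alone. The median was 0.237 (0.132 with the mean of all probe sets and 0.368 with spike-in scaling) and the camera adjusted p was 0.152. Ccl2, which attracts monocytes, rose by 1.03 ± 0.26 (2.05-fold; limma adjusted p = 0.0358). The 5 that fell were Cxcl3, a neutrophil attractant, at -2.40 ± 0.53 (-1.54 without p53 off replicate 1), Ccl20 at -1.64 ± 0.073, Ccl24, an eosinophil attractant, at -1.53 ± 0.13, Cxcl14 at -0.64 ± 0.16 and Ccl6 at -0.38 ± 0.10. Macrophage markers had a median of 0.515 in the same samples. Without p53 off replicate 1 the camera adjusted p of the list was 0.0203 (range 0.0203 to 0.823), and the limma calls were lost for Ccl2 (adjusted p = 0.0505), Cxcl14 (0.128) and Ccl6 (0.192). Quantile normalization ended the calls of Cxcl14 (0.0636) and Ccl6 (0.0781). Spike-in scaling also ended the calls of Cxcl14 (0.0516) and Ccl6 (0.121; change -0.25), and the mean of all probe sets that of Cxcl14 (0.223; change -0.37). Those of Ccl2 (0.177) and Ccl6 (0.0882) were lost without p53 off replicate 2, and those of Cxcl14 (0.076) and Ccl6 (0.111) without p53 on replicate 2. Over the alternatives the adjusted p ran from 0.00453 to 0.177 for Ccl2, from 0.0109 to 0.223 for Cxcl14, from 0.0142 to 0.192 for Ccl6 and from 0.00568 to 0.124 for Cxcl3, the last with trend and robust eBayes.

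Several genes of adhesion molecules that immune cells bind rose in p53 on. Vcam1 rose by 2.40 ± 0.074 (5.27-fold; 1.45 with the mean of all probe sets), Icam1 from 8.70 ± 0.043 to 10.28 ± 0.10 (SD, n = 2 each; 1.58 ± 0.085, limma adjusted p = 0.00051), Cd48, a ligand of an NK cell receptor, by 1.47 ± 0.071 and Icam2 by 0.84 ± 0.22 (0.50 without p53 on replicate 2). Pvr, a ligand of the NK cell receptor DNAM-1, fell by 1.22 ± 0.076. These are the 4 genes that rose and the 1 that fell among 8 measured NK cell ligands and adhesion molecules, also adjusted over the list alone (median 0.456, or 0.236 without p53 on replicate 2 0.724 without p53 on replicate 1 and 0.844 with dim genes left out; camera adjusted p = 0.152, fry adjusted p = 0.0378). Endothelial markers moved with them, at a median of 0.659. The list named 15 genes, and the ligand genes Raet1a to Raet1e, H60a and H60b were not measured. The related genes H60c and Ulbp1 were not called (limma adjusted p = 0.782 and 0.317). Most of these NK cell ligands were therefore not assessed. The call for Icam2 was lost without p53 off replicate 1 (limma adjusted p = 0.145) and 2 (0.148) and with quantile normalization (0.0505), in a range of 0.000767 to 0.148.

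Of 13 measured NK cell and cytotoxic markers 8 rose and 2 fell, with the same counts adjusted over the list alone. The granzyme gene Gzma rose by 2.56 ± 0.49 (5.88-fold; limma adjusted p = 0.0146), the NK receptor subunit gene Klrd1 by 1.57 ± 0.14 and the granule protein gene Nkg7 by 0.93 ± 0.083. Klrc1, which encodes the inhibitory NK receptor NKG2A, changed by -2.35 ± 0.14 (5.11-fold lower) and the kinase gene Txk by -0.44 ± 0.11. The list's median was 0.586 (0.377 without p53 off replicate 2) and its camera adjusted p 0.0149, with an adjusted p = 0.648 with an estimated correlation, 0.0956 by fry, 0.0725 with dim genes left out and 0.086 with spike-in scaling (range 0.00275 to 0.648). Gzma lost its call without p53 off replicate 2 (limma adjusted p = 0.0915, range 0.00048 to 0.0915) and with trend and robust eBayes (0.0834). Txk lost it without p53 off replicate 1 (0.16), p53 off replicate 2 (0.0691) and p53 on replicate 1 (0.089), and with spike-in scaling (0.0991; range 0.011 to 0.16).

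T cell markers did not pass: limma called 0 of 12, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (median 0.0503, between 0.024 and 0.106 with single arrays left out, 0.00749 with quantile normalization, -0.0244 with each array centred on its median, 0.181 with spike-in scaling and 0.244 with dim genes left out; camera adjusted p = 0.654, fry adjusted p = 0.221). The member with the smallest p was Cd3e, with a log2 change of 0.25 ± 0.076 (limma adjusted p = 0.0637), which passed with spike-in scaling (0.0164) and with the mean of all probe sets (0.0462). In the B cell and plasma cell list 1 of 11 genes rose, the receptor gene Cd22 (0.59 ± 0.074), and the same 1 adjusted over the list alone. The median was 0.0823 (0.0315 to 0.129 with single arrays left out and 0.00761 to 0.213 over 3 other scalings) and the camera adjusted p was 0.251. Of 12 neutrophil markers Csf3r, a cytokine receptor gene, rose by 0.38 ± 0.081 and Il1r2, a decoy receptor gene, fell by 0.62 ± 0.12, and these 1 and 1 also adjusted over the list alone. The median was 0.138 (0.0557 to 0.228 with single arrays left out and 0.0637 to 0.269 over 3 other scalings) and the camera adjusted p was 0.342. Both neutrophil calls were lost without p53 off replicate 1 (limma adjusted p = 0.107 and 0.0781) and 2 (0.119 and 0.097), and that of Csf3r without p53 on replicate 2 (0.0596), in ranges of 0.0091 to 0.119 and 0.00243 to 0.097.

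Macrophage and monocyte markers were higher in p53 on. The macrophage surface gene Adgre1 (F4/80) rose by 1.17 ± 0.092, the growth factor receptor gene Csf1r by 1.16 ± 0.10, the pore-forming protein gene Mpeg1 by 1.05 ± 0.071 and the lysozyme gene Lyz2 by 1.01 ± 0.14. Of 20 genes 12 rose, also adjusted over the list alone. The median was 0.515 and the camera adjusted p was 0.000193, against an adjusted p = 0.611 with an estimated correlation and 0.0378 by fry. Dendritic cell markers were higher too, with 6 of 9 genes up, also adjusted over the list alone. The median was 0.64 and the camera adjusted p was 0.000436, against an adjusted p = 0.611 with an estimated correlation and 0.00562 by fry. Zbtb46, a transcription factor gene of classical dendritic cells and endothelium, rose by 2.75 ± 0.088 (6.75-fold; 1.30 with the mean of all probe sets), the transcription factor gene Irf8 by 1.49 ± 0.072, Batf3 by 0.89 ± 0.22 (0.58 without p53 off replicate 1) and the lectin gene Cd209a by 0.82 ± 0.089. The call for Batf3 was lost without p53 off replicate 1 (limma adjusted p = 0.0664) and without p53 on replicate 2 (0.0628), in a range of 0.0105 to 0.0664.

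Genes of antigen presentation were higher together. In the MHC class II pathway H2-Aa rose by 2.32 ± 0.074 (4.99-fold), H2-Ab1 by 2.17 ± 0.088, the invariant chain gene Cd74 by 2.09 ± 0.082, H2-DMa by 1.37 ± 0.13 and H2-Eb1 by 0.68 ± 0.087. These 5 of 6 measured genes rose, also adjusted over the list alone. The median was 1.73 and the camera adjusted p was 5.44e-05, against an adjusted p = 0.611 with an estimated correlation and 0.0201 by fry. In the MHC class I pathway 9 of 10 genes rose, and 10 adjusted over the list alone. The median was 1.01 and the camera adjusted p was 2.4e-05, against an adjusted p = 0.636 with an estimated correlation and 0.0562 by fry. Nlrc5, the transcriptional activator of class I genes, rose by 1.76 ± 0.15, the immunoproteasome genes Psmb9 and Psmb8 by 1.47 ± 0.20 and 1.17 ± 0.18, and the peptide transporter gene Tap1 by 1.12 ± 0.30. Interferon-stimulated genes were higher, with 8 of 23 up and 17 adjusted over the list alone. The median was 0.45 (0.283 without p53 on replicate 2 and 0.707 without p53 on replicate 1) and the camera adjusted p was 5.44e-05, against an adjusted p = 0.648 with an estimated correlation and 0.163 by fry. The GTPase gene Gbp2 rose by 1.12 ± 0.16, Cmpk2 by 0.97 ± 0.18, Oasl2 by 0.90 ± 0.079 and the oligoadenylate synthetase gene Oas1a by 0.66 ± 0.16. Macrophage and dendritic cell markers, from cells that present antigen, moved with these lists, at medians of 0.515 and 0.64. Without p53 off replicate 2 the limma calls were lost for Tap1 (adjusted p = 0.171), Psmb8 (0.0568), Cmpk2 (0.0634) and Oas1a (0.166). They were lost without p53 off replicate 1 for Oas1a (0.0697) and without p53 on replicate 2 for Tap1 (0.0814). The ranges over the alternatives for Tap1, Psmb8, Cmpk2 and Oas1a were 0.0128 to 0.171, 0.00041 to 0.0568, 0.00667 to 0.0634 and 0.00373 to 0.166. Cmpk2 was at 0.57 and Psmb8 at 0.76 with the mean of all probe sets. Tap1 changed by 0.27 (adjusted p = 0.0797) with the mean of all its probe sets, and its adjusted p was 0.0588 with trend and robust eBayes.

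Endothelial markers were higher in p53 on: Plvap, of fenestrated endothelium, rose by 1.93 ± 0.12 (3.81-fold), the angiopoietin receptor gene Tek by 1.40 ± 0.19, Vwf by 1.02 ± 0.15 and Emcn by 0.93 ± 0.074. Of 17 genes 12 rose and 1 fell, Lyve1, a marker of lymphatic and liver sinusoidal endothelium, at -0.69 ± 0.14; 13 rose and 2 fell adjusted over the list alone. The median was 0.659 and the camera adjusted p was 0.000273, against an adjusted p = 0.648 with an estimated correlation and 0.0816 by fry. Among fibroblast, stellate cell and matrix genes, Lum was followed by the proteoglycan gene Dcn at 2.53 ± 0.26 (5.78-fold) and the growth factor receptor gene Pdgfrb at 0.93 ± 0.091. Lrat, the enzyme gene with which quiescent stellate cells store vitamin A, changed by -0.85 ± 0.21 (-0.55 with the mean of all probe sets). In that list 14 of 19 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone. The median was 0.57 and the camera adjusted p was 7.06e-06, against an adjusted p = 0.636 with an estimated correlation and 0.0555 by fry. Without p53 off replicate 1 the limma calls were lost for Lyve1 (adjusted p = 0.0748, range 0.00479 to 0.0748) and Lrat (0.113, range 0.00773 to 0.113), and that of Lrat without p53 on replicate 2 (0.0634).

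Fetal liver, progenitor and biliary genes were led by falls. Krt18 and Krt8, keratins of simple epithelia, changed by -1.61 ± 0.10 and -1.36 ± 0.10, the surface protein gene Cd24a by -1.53 ± 0.082, the biliary keratin gene Krt19 by -1.04 ± 0.15 and the transcription factor gene Sox9 by -0.81 ± 0.12. The adhesion molecule gene Epcam rose by 0.52 ± 0.072. These 5 fell and 1 rose of 12 measured, also adjusted over the list alone; the median was -0.353 (-1.04 with dim genes left out and -0.222 with spike-in scaling), the camera adjusted p 0.215 (0.0328 with spike-in scaling) and the fry adjusted p 0.0378. Of 29 hepatocyte markers 3 rose and 4 fell, and 1 rose and 3 fell adjusted over the list alone. Besides Apob, the urea cycle gene Arg1 changed by -1.10 ± 0.15, the transcription factor gene Hnf4a by -0.58 ± 0.087 (-1.54 in its probe set without likely cross-hybridization) and Ahsg by -0.45 ± 0.12. The transcription factor gene Cebpa rose by 0.87 ± 0.074, Serpina1c by 0.55 ± 0.14 and Cyp2f2 by 0.47 ± 0.13 (0.31 without p53 on replicate 1). The hepatocyte median was 0.0951 (0.0423 to 0.123 with single arrays left out and 0.0205 to 0.226 over 3 other scalings) and the mean -0.0202, with the direction up in camera (adjusted p = 0.749). Without p53 off replicate 2 the limma calls were lost for Epcam (adjusted p = 0.0514), Serpina1c (0.209), Cyp2f2 (0.225) and Ahsg (0.193). They were lost without p53 off replicate 1 for Serpina1c (0.0698) and Cyp2f2 (0.106). Without p53 on replicate 1 they were lost for Serpina1c (0.078), Cyp2f2 (0.0868) and Ahsg (0.0985). The calls of Serpina1c (0.0519) and Cyp2f2 (0.0532) were also lost with quantile normalization, that of Cyp2f2 with each array centred on its median (0.0524) and that of Ahsg with spike-in scaling (0.0783). Epcam was at 0.34 with the mean of all probe sets and changed by 0.16 (adjusted p = 0.196) in its probe set without likely cross-hybridization, and the ranges were 0.00254 to 0.196 for Epcam, 0.00868 to 0.209, 0.00722 to 0.225 and 0.0208 to 0.193 for Serpina1c, Cyp2f2 and Ahsg.

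Of 12 lysosomal genes 4 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (median 0.24, or 0.371 with spike-in scaling; camera adjusted p = 0.1, or 0.0474 with quantile normalization). Hexa, a subunit of hexosaminidase, rose by 0.64 ± 0.074, the protease genes Ctsd and Ctsb by 0.54 ± 0.077 and 0.31 ± 0.071, and the sialidase gene Neu1 by 0.28 ± 0.076, while the protease gene Ctsl fell by 0.39 ± 0.086. Macrophage markers rose in the same samples, at a median of 0.515. Apoptosis regulators held 1 gene that rose and 1 that fell of 16, also adjusted over the list alone (median 0.0595, -0.0151 with each array centred on its median and 0.191 with spike-in scaling; camera adjusted p = 0.749). Bcl2l11, which encodes the death-promoting protein BIM, rose by 0.44 ± 0.080, although 1 of its 5 probe sets passed in the other direction, and the survival gene Bcl2 fell by 0.44 ± 0.078. Neither call held with the mean of all probe sets, where Bcl2l11 was at 0.065 (limma adjusted p = 0.6) and Bcl2 at -0.15 (0.133). The calls of Ctsb, Ctsl, Neu1, Bcl2l11 and Bcl2 were lost without p53 off replicate 2, at limma adjusted p of 0.132, 0.148, 0.238, 0.053 and 0.0802, and without p53 off replicate 1, at 0.123, 0.0684, 0.13, 0.0787 and 0.0664. Without p53 on replicate 1 the calls of Ctsb (0.0555), Ctsl (0.0618) and Neu1 (0.0626) were lost, and without p53 on replicate 2 those of Ctsb (0.0598) and Neu1 (0.126). Ctsl lost its call with spike-in scaling (0.0757; change -0.26) and Ctsb with each array centred on its median (0.0705), while Ctsb was at 0.61 with the mean of all probe sets. Neu1 also lost its call with quantile normalization (0.0611), each array centred on its median (0.115), the mean of all probe sets (0.109) and trend and robust eBayes (0.0649). The ranges over the alternatives were 0.00327 to 0.132, 0.01 to 0.148, 0.0176 to 0.238, 0.00396 to 0.6 and 0.00484 to 0.133. Of 4 red blood cell and 5 platelet genes limma called 0, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. The red blood cell list had a median of 0.067 (-0.0477 to 0.0925 with single arrays left out, -0.0076 with each array centred on its median, 0.00743 with quantile normalization, -0.00541 with the mean of all probe sets and 0.198 with spike-in scaling), a camera adjusted p of 0.846 and a fry adjusted p of 0.458, and its member with the smallest p, Slc4a1, changed by 0.092 ± 0.10 (between -0.0092 and 0.19 with single arrays left out). The platelet list had a median of 0.129 (-0.0526 to 0.129 with single arrays left out and 0.0544 to 0.26 over 3 other scalings), a mean of -0.0636, the direction up in camera (adjusted p = 0.804) and a fry adjusted p of 0.663; Ppbp changed by -0.95 ± 0.41 (limma adjusted p = 0.147), by -1.62 (0.00732) without p53 off replicate 2 and by -0.29 without p53 off replicate 1.

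**Figure D2:**
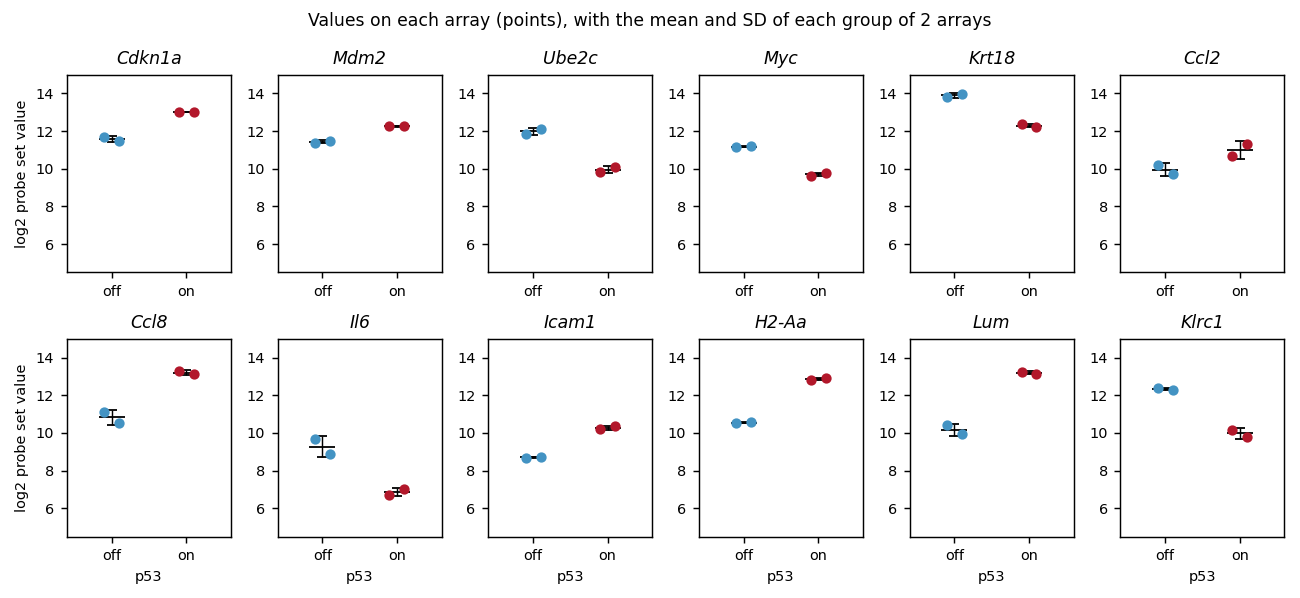
Log2 value on each array (points) with the group mean and SD (bars, n = 2 per group) for 12 named genes in p53 off and p53 on. Cdkn1a rises from a mean of 11.57 to 13.00 and Ube2c falls from 11.98 to 9.95.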

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

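The test of these probe sets was chosen after the data were seen, beside the planned test of all probe sets. Among 10092 probe sets that are not paired with exactly 1 gene here, and so stay outside the gene-level comparison, 894 were higher and 525 lower in p53 on past limma's adjusted p of 0.05. These 1419 probe sets were picked out because they hold signal that the comparison of named genes does not use. The same fit called 10272 of the 45101 probe sets, less 64 controls. The 10092 were therefore called at a lower rate than probe sets as a whole. Groups of 2 were not tested for outliers, and 1 contrast leaves no effects to compare between contrasts.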

How the results depend on the processing

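The scaling to the spike-in controls, the crossed block, the 3 added gene lists and the genes named after their values were seen were chosen after the data were seen; the other alternatives were planned. Of the 111 genes named by the rule 90 kept their direction and their side of the threshold under every alternative run for them, as did 14 of the 30 other genes and 5 of the 27 lists; the crossed block was run only for the counts of genes. All 5223 called genes kept their sign with each single array left out. That adds little, since a called change is large beside the spread within its groups. Fewer kept their sign with quantile normalization (5220), the brightest probe set without a cross-hybridization mark (5177) and the mean of all probe sets (5168). Of the calls shared with the last pair of settings, 4 of 5011 and 6 of 4311 had the opposite direction. The count of called genes then ran from 2228 to 5055, that of higher genes from 1093 to 2573 and that of lower genes from 1135 to 2711, with fewer arrays in each fit. Testing all probe sets gave 10272 calls, 5076 higher and 5196 lower, since more units are tested, and requiring a 2-fold change left 960, 496 higher and 464 lower. Spike-in scaling moved the median change of all genes from 0.023 to 0.154 and gave 4421 higher genes of 6313. Relative to that shift the epithelial genes, with a median of 0.000582 there, were lower, and their camera call stayed. Camera called 12 to 14 lists under the alternatives to the fit, 10 by fry and 0 with an estimated correlation. The estimate and its test rest on 2 residual degrees of freedom, so those 0 calls decide little. Every list called by camera misses the count of 5 lists above through that test at least. The replicate block gave 4323 calls, of which 4222 were shared with the fit without it. Deviations of same-numbered arrays correlated across genes at -0.154, and the labels do not say that the numbers pair samples. Under that block the calls of Ccl2, Oas1a, Tap1, Ctsb, Txk, Neu1, Pfkp and Adm did not hold, no list call changed, and the crossed replicate block gave 3954 calls.

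Among the named genes and the gene lists, values that turned their sign were small in the main fit except for that of Igfbp5. It went from -2.28 to 0.065 in the probe set without likely cross-hybridization. Slc4a1 was at -0.046 with the mean of all probe sets and between -0.0092 and 0.19 with single arrays left out. The median of secreted factors was 0.0911 with dim genes left out, 0.127 with spike-in scaling, and between -0.1 and 0.0834 with single arrays left out (0.0188 and 0.0834 without p53 off replicates 2 and 1). With each array centred on its median the T cell list was at -0.0244, the apoptosis list at -0.0151 and the red blood cell list at -0.0076. The red blood cell list was also at -0.00541 with the mean of all probe sets and between -0.0477 and 0.0925 with single arrays left out, and the platelet list was between -0.0526 and 0.129 there. Where no cause is named, the cause was not tested. No alternative gave a value for the gene targeted by the hairpin. Signal over background was not measured, so small changes of dim genes stay open.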

Other observations

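The tests and gene lists in this part were chosen only after the result was seen, except the 2 tests of the scaling between arrays, in which the scaling to the spike-in controls, 1 of the 3 used, was chosen after the data were seen.

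Genes of cholesterol synthesis fell together in p53 on. The isopentenyl diphosphate isomerase gene Idi1 changed by -2.43 ± 0.11 (SE, n = 2 against 2; 5.40-fold lower; limma adjusted p = 0.00038). The sterol desaturase gene Sc5d changed by -2.46 ± 0.14, the lanosterol demethylase gene Cyp51 by -2.40 ± 0.18 and the farnesyl diphosphate synthase gene Fdps by -2.25 ± 0.16; with the mean of all probe sets Sc5d was at -0.94, Cyp51 at -1.58 and Fdps at -1.14. Of 20 measured genes 18 fell over all genes and the same 18 adjusted over the list alone (median -1.36, camera adjusted p = 2.36e-13 over the 3 added lists, adjusted p = 0.238 with an estimated correlation, fry adjusted p = 0.0136). In the same samples bright epithelial genes had a median of -0.64 and bright macrophage and mast cell genes medians of 0.828 and 2.35, and a lower tumor share was not tested for the cholesterol genes.

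Mast cell genes rose in p53 on, among them the tryptase genes Tpsab1 and Tpsb2 by 2.79 ± 0.44 and 2.59 ± 0.30 (1.34 for Tpsb2 with the mean of all probe sets), the chymase gene Cma1 by 2.70 ± 0.48 and the carboxypeptidase gene Cpa3 by 2.53 ± 0.31. Of 15 measured genes 10 rose, and 12 adjusted over the list alone (median 1.49, camera adjusted p = 6.03e-06, adjusted p = 0.273 with an estimated correlation, fry adjusted p = 0.0495). Cma1 lost its limma call without p53 off replicate 2 (adjusted p = 0.0559) and with trend and robust eBayes (0.0668; range 0.00268 to 0.0668). Of 30 epithelial genes 13 fell and 2 rose, also adjusted over the list alone (median -0.13, or -0.198 without p53 on replicate 1, camera adjusted p = 0.000472, adjusted p = 0.174 with an estimated correlation, fry adjusted p = 0.0113). The desmosome gene Pkp2 changed by -2.75 ± 0.14 and the tight junction gene Cldn4 by -1.34 ± 0.12, while the junction gene Jup rose by 0.76 ± 0.077.

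Markers of several host cell types rose. The lowest median of the endothelial, fibroblast, macrophage and dendritic cell lists over 3 other scalings was 0.44. The deposited values were already quantile normalized, and these scalings put the median change of all genes between -0.0518 and 0.154. A shift between arrays of that size is argued against as the source of the rises, and a larger or uneven one was not tested. A lower share of tumor cells would raise the markers of every other cell type alike; over markers in the brighter part of all genes, medians were 0.828 for macrophages (14 genes), 0.683 for endothelium (12), 0.57 for fibroblasts (19) and 2.35 for mast cells (9). Other medians rest on few genes: 1.07 for dendritic cells and -0.192 for neutrophils on 4 each, 0.249 for T cells and 0.397 for B cells on 2 each, and 0.638 for NK cells on 3, whose changes ran from -2.35 (Klrc1) to 2.55 (Gzma). A permutation test between the 8 types of the lists fixed in advance gave p = 0.062, or 0.024 without Klrc1. Its p was 0.35 over the 3 types with at least 10 bright genes. The result for the 8 types thus turns on Klrc1, which is no sure measure of NK cells here. A lower tumor share alone would also put no type below 0, and the neutrophil median was, on 4 genes. Genes are the units of the permutation test and are not independent, so its p does not measure the spread between samples. Mast cell genes were listed because they rose, so the p of 0.012 with them (0.0055 also without Klrc1) decides nothing; a lower tumor share stays open, with bright epithelial genes at a median of -0.64, as does restored p53 drawing in or activating host cells.

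Cell cycle genes fell. The highest median of G2/M and mitosis genes over the same 3 scalings was -0.811, with spike-in scaling. It was -0.916 with the planned quantile normalization. A shift between arrays of the size these scalings give is argued against, and a larger or uneven one was not tested. Dilution of tumor cells by host cells would lower epithelial genes as much as mitosis genes, and the median of bright epithelial genes minus that of mitosis genes was 0.301, with a bootstrap 95% interval of -0.403 to 1. The interval reflects the spread between genes, not between samples. It holds 0, so this test cannot tell dilution from a fall within tumor cells. Its epithelial list was chosen after the data were seen and holds Krt8, Krt18 and Krt19, which fell. Only bright members were used, whereas the mitosis list (median -0.942) was not cut. All 30 epithelial genes, dim ones included, had a median of -0.13. A lower rate of division under restored p53 may be part of the fall of cell cycle genes. It was not tested apart from dilution, doxycycline or time.

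Klrc1 fell, as did Txk, while 8 of the NK cell genes rose. An artifact of a single probe set is argued against: the other probe set of Klrc1 changed by -2.68 ± 0.26, beside -2.35 ± 0.14 for the one used. In p53 off the mean log2 value of Klrc1 was 12.33, against 6.79 for Klrd1, 6.59 for Nkg7 and 8.76 for Gzma. Levels of different probe sets compare only roughly, and the cells that gave the Klrc1 signal were not determined. The fall of Klrc1 is therefore no measure of NK cells. The number of NK cells stays open, and no biological explanation was tested.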
